A study of Mus musculus with 2 samples.

How the data were processed

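Per the labels' protocols, 250000 4T07 cells carrying tdTomato-p27K were placed in the mammary fat pad of mice expressing Kaede. Tumours were embedded in 2% agarose and sliced at 300 µm. Chosen areas were photoconverted at 405 nm, slices were digested for 15 min, and live cells positive for green and red Kaede were sorted. Consecutive slices served first for areas without tdTomato and then for areas with cells high in p27K, per the series' design text. Cells of QCC areas and proliferative areas carried hashtag 7 and hashtag 8 in library 1 and hashtag 9 and hashtag 10 in library 2, per the labels, and were pooled before capture.

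The deposited values are whole-number UMI counts per gene or hashtag and barcode, made with Cell Ranger 3.1.0 per the file headers, against mm10 per the submitters' processing notes, which also name Seurat 4.0.3. Each deposited matrix holds 31053 genes, 2 hashtags and all 6794880 barcodes, so no cells had been called in it. A cell annotation by the authors was not used here. The libraries held 124139398 and 128322317 gene UMIs, with 9735306 and 9300536 hashtag UMIs for QCC and proliferative areas in library 1 and 8502448 and 11667465 in library 2.

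Cells were barcodes with at least 1000 gene UMIs, 500 genes and at most 10% mitochondrial UMIs, which gave 4972 and 4679. For each hashtag a Gaussian mixture of 2 components on log10 of the count plus 1 marked a cell as positive, at a smallest count of 160 and 147 in library 1 and 151 and 133 in library 2. Cells positive for exactly 1 hashtag were kept. Cells with both (880, or 17.7%, and 593, or 12.7%) or none (133, or 2.68%, and 89, or 1.90%) were left out. Scrublet, with an expected rate of 0.06, marked 0 cells in both libraries and so did not work here, although doubly tagged cells had a median of 39730 and 40540 UMIs against 14960 and 12980 in singly tagged cells. The doubly tagged cells imply 884 (22.3%) and 741 (18.5%) further doublets within an area among the 3959 and 3997 singly tagged cells. These were kept in the main result, and an alternative chosen after seeing the data left out as many singly tagged cells, those with the largest share of doubly tagged cells among their neighbours. Per area, QCC and proliferative cells held 44414044 and 29522199 UMIs in library 1 and 32347418 and 50848333 in library 2, with median mitochondrial shares of 5.45% and 5.13% and of 4.91% and 4.63%.

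Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15). T and NK clusters were clustered again in the same way. A cluster could be called X-like only for a class with enough of its markers, fixed before the data were examined, detected in the cluster. Of such classes, the one whose markers had the highest mean standardised expression gave the name. The cluster stayed unnamed if more of its 10 leading genes marked another cell family than its own class. It also stayed unnamed if it was shallow and none of them marked its own. Clusters c8, c20 and cT3 stayed unnamed, and c20 was led by Trdc and Il17a. T and NK cells counted as 1 family, so sub-cluster cT9 stayed NK cell-like although it was led by Trdc and had no NK marker among its leading genes; it held 1.33% of that class in QCC against 5.88% in proliferative areas of library 1 and 6.35% against 11.2% in library 2. The gene lists, tests, rules for named genes and, except where stated, alternative settings were likewise fixed before the data were examined.

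UMI counts were summed per library, area and class. Classes with at least 20 cells in each of the 4 sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, R 4.3.3), with library as a block and QCC areas compared with proliferative areas, and p-values were adjusted by Benjamini-Hochberg within a class at 0.05. The block rests on the labels, which say that both areas were tagged and pooled in 1 library. The check of this pairing was a correlation across genes, which are not independent replicates, of the deviations of same-numbered sums from their area means. It was 0.658 for all cells, 0.389 in CD8 T cell-like and 0.521 in macrophage/monocyte-like cells, and from 0.0608 to 0.232 in the other 5 sets tested. The fit leaves 1 residual degree of freedom per gene, so the spread is largely borrowed across genes. An exact permutation of 2 against 2 values that ignores the pairing cannot go below p = 0.33. One that keeps the pairing has fewer arrangements and a higher floor. Standard errors are the absolute log2 fold divided by the square root of F. Shares were tested with edgeR on cell counts, with all singly tagged cells of a sum as the offset, and carry exact binomial (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only.

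Gene lists were tested with limma 3.58.1 camera on voom-weighted log2 CPM (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation, which rests on 1 residual degree of freedom. With the estimated correlation no list passed in any of the 8 sets of sums tested; fry, which asks whether a list moves on balance in 1 direction, gave adjusted p-values from 0.496 to 0.983 over the lists in all cells apart from MHC class II presentation (0.028, all-cell median -0.28). The lists reported are type I interferon response, interferon gamma response, hypoxia targets, glycolysis, proliferation, MHC class I and class II presentation, T cell effector function, T cell exhaustion, dendritic cell maturation, immunosuppressive myeloid, dissociation and heat shock, monocyte recruitment chemokines, extracellular matrix and contractile fibroblast, inflammatory fibroblast and inflammatory myeloid genes.

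Named genes were, per class, the 10 largest changes in each direction among genes past the threshold, of the same direction in both libraries and at 20 CPM or more on average, up to 8 list members past the threshold per list, the 4 most abundant members of lists discussed, and, where fewer than 5 genes passed, 5 genes in each direction with the smallest p as values. Classes with at least 8 cells per sum were added after seeing the data. Free RNA was measured in droplets of 1 to 100 UMIs. For each gene most abundant there, its share in the class was divided by its share in these droplets. The bound for a class is the 10th percentile of these ratios. It approximates the largest share of UMIs that this profile could supply, and genes below that percentile would allow less.

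Alternatives were no replicate block, floors of 500 and 2000 UMIs, at most 20% mitochondrial UMIs, a hashtag ratio rule (at least 10 counts, 3-fold), no filter on low counts, DESeq2 1.42.0, immune classes as the denominator, Leiden resolution 0.6, an estimated correlation, DESeq2 size factors for the lists, background genes left out (for genes in a class, not for lists), and each sum left out in turn. The tests were tested on simulated data with 200 changed genes in 10 simulations. 2-fold and 4-fold changes were recovered at 49.1% and 86.0% in all cells, 66.5% and 95.5% in CD8 T cell-like, 40.5% and 92.5% in cDC2-like, 63.2% and 94.4% in macrophage/monocyte-like, 19.2% and 83.3% in mDC-like and 34.8% and 88.4% in NK cell-like cells, 8.36% and 67.1% in c8 and 38.2% and 83.8% in cT3. Of the calls on simulated data, from 5.99% (cT3) to 14.1% (c8) were false, with 12.8% in all cells, 6.81% in CD8 T cell-like, 7.72% in cDC2-like and 10.7% in macrophage/monocyte-like cells. Coordinates are from GENCODE M21 on GRCm38, the mm10 assembly. Median depth over all classes together was higher in QCC areas of both libraries, though not within every class, which sums and TMM scale for but which can set how many genes reach detection in a cell.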

Results

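Cells infiltrating 4T07 tumours in mice were profiled by droplet single-cell RNA sequencing in 2 libraries. 4T07 is a mouse mammary carcinoma line, and the injected cells carried tdTomato-p27K, a reporter that accumulates in cells that have left the cell cycle. The hosts expressed Kaede, a fluorescent protein that turns from green to red under violet light, so that cells in a chosen area of a tumour slice could be marked by light, sorted and profiled (PADME-seq). Each library pooled, under 2 hashtag antibodies, cells marked in areas of quiescent cancer cells (QCC areas) and cells marked in proliferative areas. The comparison asks how the infiltrate of QCC areas differs from that of proliferative areas. Per the series' design text, consecutive slices served first for areas without tdTomato and then for areas with cells high in p27K. Differences of slice or order of handling thus cannot be told apart from differences of area, with or without a library block. The libraries held 124139398 and 128322317 gene UMIs. Singly tagged cells numbered 2075 from QCC areas and 1884 from proliferative areas in library 1, and 1332 and 2665 in library 2. Their median depth was 16499 and 13484 UMIs in library 1 and 17346.5 and 11623 in library 2, so the median over all classes together was higher in QCC areas of both. It was not higher within every class, and was 13150.5 against 14145 in CD8 T cell-like cells of library 2. Differences below are log2 values of QCC over proliferative areas with the standard error (SE) of the fit over n = 2 libraries, followed where given by the values within library 1 and library 2. The labels do not say that the libraries came from separate animals. The edgeR p-values thus measure at most the spread between these samples, which may be technical. That spread was largely borrowed across genes, and wholly so in CD8 T cell-like cells. Camera p-values at the preset correlation compare the genes of a list with the other genes. In them genes act as the replicates, so they do not measure the spread between libraries.

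The infiltrate was dominated by macrophage/monocyte-like cells, which made up 66.7% of QCC cells and 61.1% of proliferative cells in library 1 and 38.8% and 34.7% in library 2. CD8 T cell-like cells made up 11.0% of QCC cells (95% exact binomial interval 9.67 to 12.4) against 5.94% of proliferative cells (4.92 to 7.11) in library 1, and 17.4% (15.4 to 19.6) against 9.16% (8.09 to 10.3) in library 2. The fitted difference for these cells was 0.91 ± 0.38 (SE, n = 2 libraries), with an adjusted p of 0.194 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Plasmacytoid dendritic cells (pDC) are a professional source of type I interferon. pDC-like cells made up 0.627% (0.334 to 1.07) against 3.13% (2.39 to 4.02) in library 1 and 1.58% (0.979 to 2.40) against 5.55% (4.71 to 6.49) in library 2. Their difference was -2.05 ± 0.44 with an adjusted p of 0.125. Plasma cell-like cells made up 0.916% against 2.55% in library 1 and 0.225% against 1.01% in library 2 (-1.70 ± 0.49, adjusted p = 0.125). B cell-like cells made up 0.193% against 1.11% in library 1. In library 2 they were 0 of 1332 QCC cells, which allows a share of up to 0.225% at 3 counts (exact binomial upper limit 0.277%), against 0.525%. Natural killer (NK) cell-like cells made up 3.61% against 6.32% and 4.73% against 16.4% (-1.30 ± 0.46, adjusted p = 0.142). Neutrophil-like cells made up 0.867% against 3.24% and 2.55% against 4.95% (-1.40 ± 0.47, adjusted p = 0.142).

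None of the 17 classes passed the adjusted threshold over all cells, and 5 had an unadjusted p under 0.05. With the immune classes alone as the denominator, the pDC-like (-1.98) and B cell-like (-2.95) classes passed, both with an adjusted p of 0.027 in the same edgeR test. Mast cell/basophil-like cells made up 1.69% against 0.637% in library 1 and 6.23% against 4.05% in library 2 (0.95 ± 0.45, adjusted p = 0.231). The difference changed sign without QCC areas of library 2 (-0.48) and without proliferative areas of library 1 (-0.0384), in fits that have no library block. That class joined a cluster led by Mcpt1, with 32 QCC against 7 proliferative cells in library 1 and 63 against 24 in library 2. Its other part was a cluster led by Mcpt8, with 3 against 5 and 20 against 84. The conventional dendritic cell class cDC1 stood at 4.43% against 5.04% in library 1 and 0.601% against 4.02% in library 2. The unnamed keratin-led cluster c8 stood at 1.16% against 1.27% and at 12.8% against 5.03%. Whether c8 held tumour cells that passed the sort was not settled here. It counts in the denominator of the shares over all cells, and it held 6931973 of the 32347418 UMIs of QCC areas of library 2. Intervals cover counting error only. On simulated counts the share test recovered 33% of 4-fold changes, and the sort for photoconverted cells set which cells could enter.

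**Figure D1:**
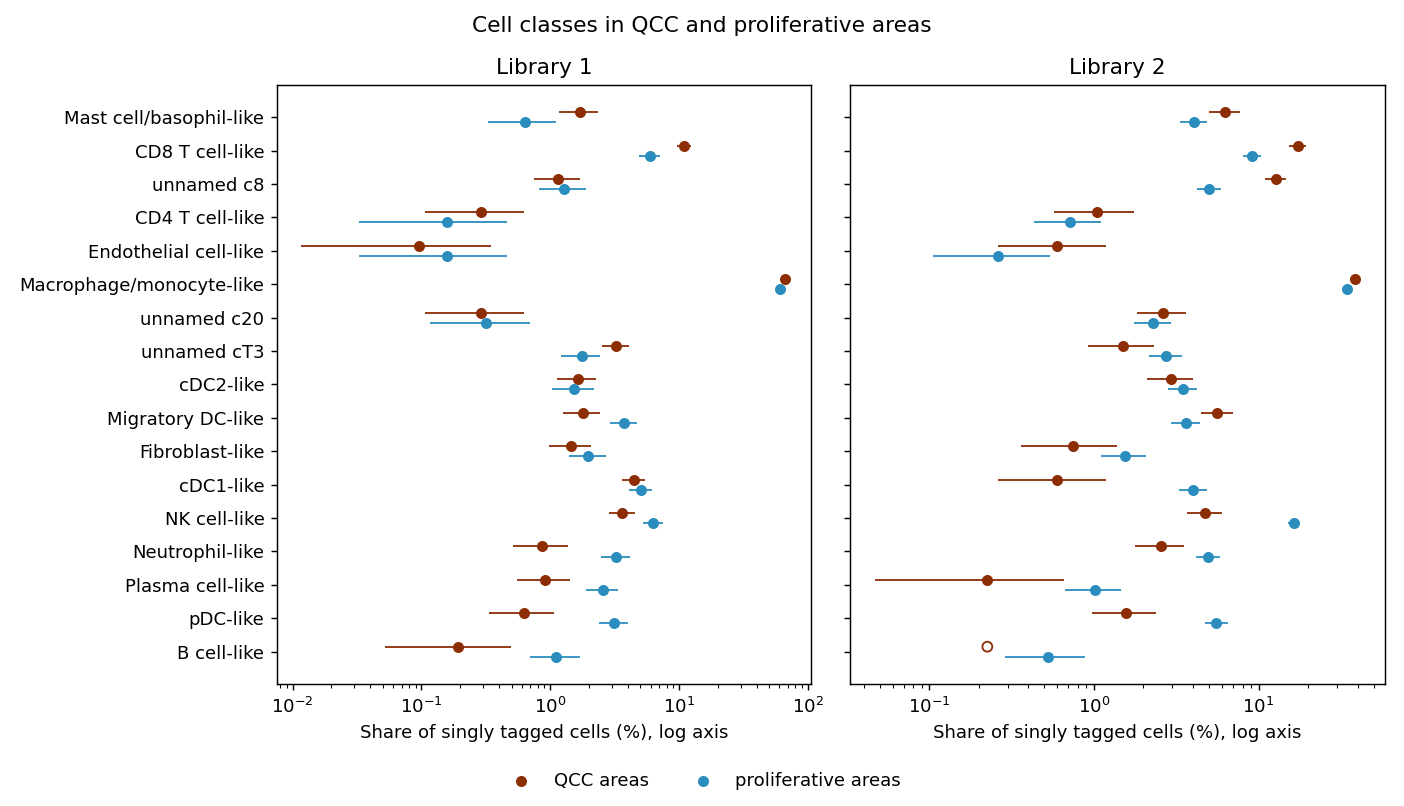
Share of singly tagged cells (%, log axis) in each class, for QCC and proliferative areas of library 1 (left) and library 2 (right), with exact binomial 95% bars; an open symbol marks 0 cells, placed at the share 3 cells would give. pDC-like cells lay at 0.627% against 3.13% in library 1 and at 1.58% against 5.55% in library 2.

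Summed over all cells of an area, both fibroblast lists and the type I interferon list were lower in QCC areas. Genes known from mast cells were among the highest and genes known from plasma cells among the lowest of those that passed, although no list of either was fixed or tested. Tph1, the enzyme of serotonin synthesis in mast cells, rose by 2.40 ± 0.16 (SE, n = 2 libraries; 2.12 and 2.59 within the libraries; adjusted p = 0.019). The mast cell proteases Tpsab1 (1.96 ± 0.19), Mcpt1 (1.83 ± 0.16), Mcpt2 (1.81 ± 0.14), Cma1 (1.60 ± 0.15) and Cpa3 (1.23 ± 0.11) rose with it. The plasma cell transcripts Iglv1 (-3.11 ± 0.15), Mzb1 (-2.81 ± 0.31) and Igkc (-2.11 ± 0.23) fell. The pDC transcript Klk1 fell by 2.09 (SE 0.12). In the list of extracellular matrix and contractile fibroblast genes 5 of 23 measured members fell, among them the collagens Col3a1 (-2.24 ± 0.13) and Col1a1 (-1.92 ± 0.20). Adjusted over the list alone, 14 fell and 1 rose, and the list median was -1.04 (camera adjusted p = 4.83e-11, adjusted p = 0.506 with an estimated correlation). In the inflammatory fibroblast list 3 of 20 fell, including the alarmin Il33 (-2.58 ± 0.23) and complement C3 (-1.58 ± 0.14). Adjusted over the list alone, 10 fell and 2 rose (median -1.31, camera adjusted p = 5.75e-08, adjusted p = 0.506 with an estimated correlation).

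Genes that cells switch on after sensing interferon alpha or beta (the type I interferon response list) fell in the sums over all cells. Their median was -0.69 (-0.65 and -0.77 within the libraries), and 3 of 20 members passed over all genes and 18 adjusted over the list alone. The members that passed were Irf7 (-1.09 ± 0.11), Isg15 (-1.09 ± 0.12) and Ifit1 (-1.05 ± 0.11). The camera adjusted p was 5.56e-21, and the adjusted p = 0.506 with an estimated correlation. The dendritic cell maturation list also fell (median -0.50, camera adjusted p = 6.91e-07, adjusted p = 0.506 with an estimated correlation), with 0 of 18 members past the threshold over all genes in edgeR and 9 adjusted over the list alone. For that list the within-library medians were -0.40 and -0.41. Over 14128 genes, 8 rose and 65 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all 73 in the same direction in both libraries. DESeq2 called 35 higher and 213 lower. Leaving out any 1 of the 4 sums, with a fit that then has no library block, left 0 genes, and the full fit without the block also called 0. Changes in these sums hold differences of cell makeup as well as differences within cells. The near-identical proteases Mcpt1 (ENSMUSG00000022227, chromosome 14, 56017971 to 56020384) and Mcpt2 (ENSMUSG00000022226, 56042041 to 56044642) and the immunoglobulin genes can share reads, so their separate values are uncertain. Tph1 (ENSMUSG00000040046) lies on chromosome 7 from 46644641 to 46672537.

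In CD8 T cell-like cells of QCC areas the granzymes Gzmf and Gzmb were higher, the glycolysis list was higher and the proliferation list lower, while the hypoxia list rose through library 2 alone. Gzmf, a cytotoxic granule protease, rose by 1.25 ± 0.12 (SE, n = 2 libraries; 1.00 and 1.45 within the libraries; adjusted p = 1.94e-20), and Gzmb, the main granzyme of killer T cells, by 0.68 ± 0.12 (0.81 and 0.58; adjusted p = 1.56e-05). Gzmb changed sign without QCC areas of library 2 (-0.79) and without proliferative areas of library 1 (-0.12), in fits that have no library block. In the effector list 2 of 19 measured members passed, Gzmb and Gzma, and 3 adjusted over the list alone. Gzma was at 57 against 0 UMIs in library 1, so its fold is not well set. Gzmc (2.34 and 0.38) and Gzmd (2.11 and 0.20) passed mostly through library 1, and these granzymes are near-identical copies whose reads may be split. Gzmc also changed sign without QCC areas of library 2 (-0.92) and without proliferative areas of library 1 (-0.34), and lost its call in DESeq2 (1.35). The effector list had a median of 0.17 (0.18 and 0.22; camera adjusted p = 0.0122, adjusted p = 0.550 with an estimated correlation). Of the exhaustion list, 3 of 20 members rose, the inhibitory receptor Havcr2 (0.65 ± 0.14, 1.08 and 0.48), Cd244 (0.94 ± 0.23) and Rgs16 (0.46 ± 0.12). Nr4a3, a transcription factor induced by T cell receptor signalling, fell by 0.95 (SE 0.24). The exhaustion list as a whole did not pass (median 0.12, camera adjusted p = 0.0673), with 4 members higher and 2 lower adjusted over the list alone. Tcf7, the transcription factor of memory-like T cells, fell by 2.27 (SE 0.45), from low counts of 5 against 9 and 7 against 53 UMIs.

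Of the hypoxia targets in CD8 T cell-like cells, 5 of 21 measured members rose and 10 adjusted over the list alone. The lipid droplet protein Hilpda rose by 0.79 ± 0.14 in both libraries (0.56 and 0.90; adjusted p = 1.1e-05), while Ndrg1 (0.17 and 1.05), Bnip3 (-0.15 and 1.24) and Ankrd37 (0.18 and 0.77) moved mainly in library 2. The list median was 0.42 (-0.04 in library 1 and 0.56 in library 2), and 9 members had the same sign in both libraries. The camera adjusted p was 3.63e-10 (adjusted p = 0.550 with an estimated correlation). Of the glycolysis list, 2 of 16 members rose, the glucose transporter Slc2a3 by 0.56 ± 0.14 and the aldolase Aldoa by 0.44 ± 0.12. Adjusted over the list alone 3 rose (median 0.27, camera adjusted p = 5.79e-06, adjusted p = 0.550 with an estimated correlation). The proliferation list fell (median -0.34, -0.18 and -0.38; camera adjusted p = 1.31e-13, adjusted p = 0.550 with an estimated correlation). Over all genes 3 of its 20 members were lower, including Tuba1b (-0.46 ± 0.12) and the thymidylate synthase Tyms (-0.44), and 14 adjusted over the list alone. The cycling sub-clusters held less of the class in QCC areas, cT4 (led by Hist1h2ae and Ube2c) 14.9% against 17.9% in library 1 and 24.6% against 29.5% in library 2, and cT10 (with Rrm2 and Tyms) 5.26% against 7.14% and 0.862% against 9.84%. The heat shock and dissociation list also rose (median 0.16, 0.42 and -0.11; camera adjusted p = 8.64e-04, adjusted p = 0.550 with an estimated correlation). Of its 20 members 2 passed, Hspa1a (0.33 and 1.84) and Hspa1b (0.30 and 1.81), copies that share reads, and 3 adjusted over the list alone. In the same cells the type I interferon list was lower (median -0.13, camera adjusted p = 0.0122, adjusted p = 0.550 with an estimated correlation), with 1 of 17 members past the threshold, Ifit1 (-0.93 ± 0.25), and 4 lower and 1 higher adjusted over the list alone. Sub-cluster cT6, led by Gzmf, held 5.70% of these cells in QCC against 3.57% in proliferative areas of library 1 and 33.2% against 17.6% in library 2.

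Over 8948 genes in CD8 T cell-like cells, 76 rose and 86 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 149 of the 162 in the same direction in both libraries. The spread was borrowed wholly across genes there, and DESeq2 called 6 higher and 2 lower, among them Fcer1g, Gzmf, Gzmb and Lgals3. Fits without 1 sum called 3 genes without QCC areas of library 1, 48 without QCC areas of library 2, 0 without proliferative areas of library 1 and 1 without proliferative areas of library 2. The full fit without the library block called 0. Without proliferative areas of library 2 the hypoxia (adjusted p = 0.362) and proliferation (adjusted p = 0.408) lists no longer passed in camera, and without QCC areas of library 2 glycolysis (adjusted p = 0.375) and type I interferon (adjusted p = 0.907) no longer passed. Type I interferon also ended without proliferative areas of library 1 (0.517) and without a filter on low counts (0.0678). The heat shock list ended without QCC areas of library 1 (adjusted p = 0.763), proliferative areas of library 1 (0.0825) and proliferative areas of library 2 (0.0541). The effector list ended in the fit without the library block (adjusted p = 0.292), and without proliferative areas of library 1 (0.15) or of library 2 (0.692), and it changed sign without QCC areas of library 1 (0.163). Free RNA of the droplets could supply 5.37% and 4.86% of the UMIs of this class in QCC and proliferative areas of library 1 and 1.59% and 2.35% in library 2. For Fcer1g (1.27 ± 0.13) and Apoe (0.60) it could supply over 50% in an area. Gzma met the same rule, but its 0 UMIs in proliferative areas of library 1 are enough to meet it. The rule thus says nothing about the source of Gzma. Gzmf (ENSMUSG00000015441) lies on chromosome 14 from 56205263 to 56211417, Gzmb (ENSMUSG00000015437) from 56258838 to 56262260, and Hilpda (ENSMUSG00000043421) on chromosome 6 from 29272488 to 29275446.

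**Figure D2:**
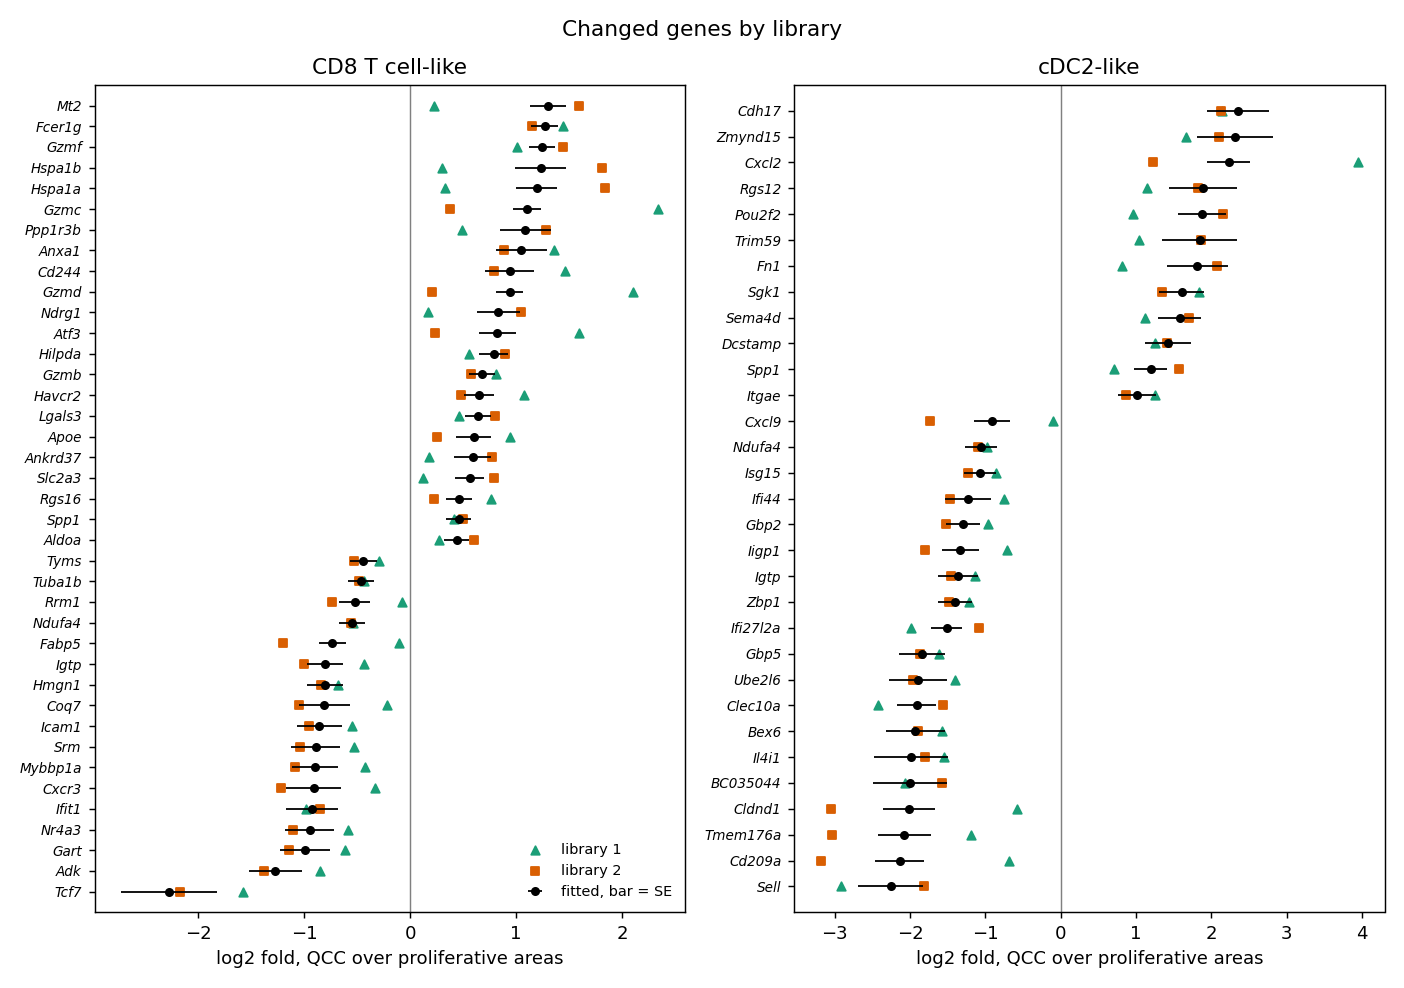
Log2 fold of changed genes, QCC over proliferative areas, in CD8 T cell-like (left) and cDC2-like (right) cells; triangles are library 1, squares library 2, and black points the fitted value with its SE, for genes of the same sign and at least 1 UMI in every sum. Gzmf lay at 1.00 and 1.45 and Clec10a at -2.42 and -1.57.

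In cDC2-like cells, a dendritic class that presents antigen to CD4 T cells, both interferon lists were lower in QCC areas. Some lectins were among the genes that passed, although no list of lectins was fixed or tested. Isg15, an interferon-induced ubiquitin-like protein, fell by 1.07 (SE 0.21, n = 2 libraries). Gbp5, an interferon-induced GTPase, fell by 1.84 (SE 0.31). Ifi27l2a fell by 1.51 (SE 0.21; -1.98 and -1.08 within the libraries; adjusted p = 4.6e-06). For the type I interferon list the median was -0.86 (-0.46 and -0.91; camera adjusted p = 1.26e-14, adjusted p = 0.653 with an estimated correlation). Of 19 measured members 4 were lower and 10 adjusted over the list alone. The interferon gamma list, genes induced by the cytokine of T and NK cells, had a median of -0.73 (-0.23 and -0.63; camera adjusted p = 9.92e-13, adjusted p = 0.653 with an estimated correlation). Of 19 measured members 6 were lower, including Igtp (-1.36), Iigp1 (-1.33) and Gbp2 (-1.30), and 11 adjusted over the list alone. Among them were Cxcl9 (-0.91) and Cxcl10 (0.25 and -5.06), chemokines that attract T cells, the latter through library 2 alone. Neither was firm. Cxcl9 changed sign without QCC areas of library 2 (0.11), and it lost its call at a similar fold in DESeq2 (-0.96, adjusted p = 1.00), at a floor of 2000 UMIs (-0.91, 0.246), with up to 20% mitochondrial UMIs (-0.77, 0.0692) and under the hashtag ratio rule (-0.91, 0.0764). The MHC class II list rose slightly (median 0.23, camera adjusted p = 0.0104, adjusted p = 0.653 with an estimated correlation), with 0 of 12 members past the threshold over all genes in edgeR and 2 adjusted over the list alone.

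The lectin Clec10a fell by 1.91 (SE 0.26; -2.42 and -1.57; adjusted p = 3e-06). Cd209a fell by 2.14 (SE 0.33; -0.68 and -3.18). Both are markers that named the cDC2-like class. Cd209d had 0 UMIs in QCC areas against 27 in library 1 and 209 in library 2, at least 10.9-fold and 35.2-fold lower with a floor of 3 counts per library; reads of the Cd209 family can be shared. The adhesion molecule Cdh17 rose by 2.36 ± 0.42 (2.14 and 2.13), and the neutrophil chemokine Cxcl2 by 2.23 ± 0.29 (3.94 and 1.22; adjusted p = 1.1e-06). The transcription factor Pou2f2 (1.88) and the secreted phosphoprotein Spp1 (1.19 ± 0.22) rose too. Clec10a (ENSMUSG00000000318) lies on chromosome 11 from 70156197 to 70170834, Cd209a (ENSMUSG00000031494) on chromosome 8 from 3743397 to 3748984, and Cxcl2 (ENSMUSG00000058427) on chromosome 5 from 90903871 to 90905938. Over 5394 genes, 25 rose and 52 fell in edgeR's quasi-likelihood test, 75 of the 77 in the same direction in both libraries, and DESeq2 called 1 higher and 2 lower. The class held as few as 29 cells in a sum, and free RNA could supply 45.4% and 59.2% of its UMIs in library 1. Genes that free RNA could supply by over 50% included 44 of the 77 called. Without them, and adjusted anew over the rest, 18 were higher and 27 lower, 33 of these also called in the main fit. Isg15, Gbp5, Clec10a, Cd209a, Cdh17 and Pou2f2 were among those called, and Ifi27l2a and Cxcl2 among those left out. Each fit without 1 sum called fewer genes than the main fit, and the full fit without the block called 1. The MHC class II list ended without QCC areas of library 1 (adjusted p = 0.504), without those of library 2 (0.0667) and without proliferative areas of library 2 (0.907).

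In macrophage/monocyte-like cells the type I interferon list was lower in QCC areas of both libraries. Its median was -0.89 (-0.76 and -0.94), and all 20 members had the same sign in both libraries. Of these 1 passed over all genes and 19 adjusted over the list alone (camera adjusted p = 6.99e-26, adjusted p = 0.667 with an estimated correlation). Ifit1, an interferon-induced RNA sensor, fell by 1.44 (SE 0.11, n = 2 libraries; -1.43 in each; adjusted p = 0.04), and Slfn5 fell by 1.39 (SE 0.11). Irf7 was at -1.25 ± 0.11 (adjusted p = 0.0529) and Isg15 at -1.32 ± 0.12 (adjusted p = 0.0554). The acute phase protein Saa3 fell by 2.88 (SE 0.16; -2.83 and -2.86; adjusted p = 0.0189). Tmem176a (-2.52 ± 0.16) and Gm15056 (-2.73 ± 0.21) fell with it. The interferon gamma list had a median of -0.88 (-0.20 and -1.42; camera adjusted p = 6.53e-12, adjusted p = 0.667 with an estimated correlation), with 0 of 19 members past the threshold over all genes and 1 adjusted over the list alone. The MHC class I list had a median of -0.36 (-0.17 and -0.58; camera adjusted p = 3.5e-06, adjusted p = 0.667 with an estimated correlation), with 0 of 15 past either. The proliferation list rose (median 0.29, 0.33 and 0.19; camera adjusted p = 1.88e-08, adjusted p = 0.667 with an estimated correlation), with 0 of 20 members past either. The immunosuppressive myeloid list did not pass (median 0.00, -0.19 and 0.08; camera adjusted p = 0.969), with 0 of 17 members past the threshold over all genes and 1 higher and 1 lower adjusted over the list alone. Values that did not pass included the matrix protein Fn1 (1.23 ± 0.18, adjusted p = 0.14) and the monocyte chemokine Ccl2 (0.82 ± 0.13, adjusted p = 0.15).

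Over 11964 genes in macrophage/monocyte-like cells, 0 rose and 7 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1166 at an unadjusted p under 0.05, and DESeq2 called 9 higher and 77 lower. With neighbour doublets left out, or with genes that free RNA could supply left out, 0 genes passed. At most 4 passed at the other floors and with up to 20% mitochondrial UMIs, and 1 under the hashtag ratio rule, while without a filter on low counts 198 rose and 509 fell. On simulated counts of this class without any change the test called 4.4 genes on average, against the 7 called here. The other 2 genes, chosen after their values were seen, were the B cell chemokine Cxcl13 (17 against 1463 UMIs in library 1, 0 against 3 in library 2) and Dmkn (3 against 34, 10 against 377). The clusters that held the class differed: c0 held 3.03% of it in QCC against 15.5% in proliferative areas of library 1 and 8.32% against 66.8% in library 2. Cluster c3 held 33.7% against 10.2% in library 1 and 4.26% against 1.08% in library 2. Cluster c5 held 2.02% against 2.17% in library 1 and 58.2% against 11.4% in library 2. The cycling cluster c6, led by Ube2c, held 15.9% against 9.81% in library 1 and 11.0% against 6.17% in library 2, and the proliferation list was not tested apart from this mix. Fits without 1 sum called 62, 12, 164 and 48 genes without QCC areas of library 1, of library 2, and proliferative areas of library 1 and of library 2, and the fit without the block 0. The proliferation list ended without QCC areas of library 1 (adjusted p = 0.152), and MHC class I without QCC areas of library 2 (0.565) and proliferative areas of library 1 (0.155). Free RNA, shared by both areas of a library, had a profile so near to this class that it could supply over 50% of the counts of 11874 of the 11964 genes. Ifit1 (ENSMUSG00000034459) lies on chromosome 19 from 34640871 to 34650009, Saa3 (ENSMUSG00000040026) on chromosome 7 from 46711998 to 46715700, and Tmem176a (ENSMUSG00000023367) on chromosome 6 from 48840919 to 48847071.

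**Figure D3:**
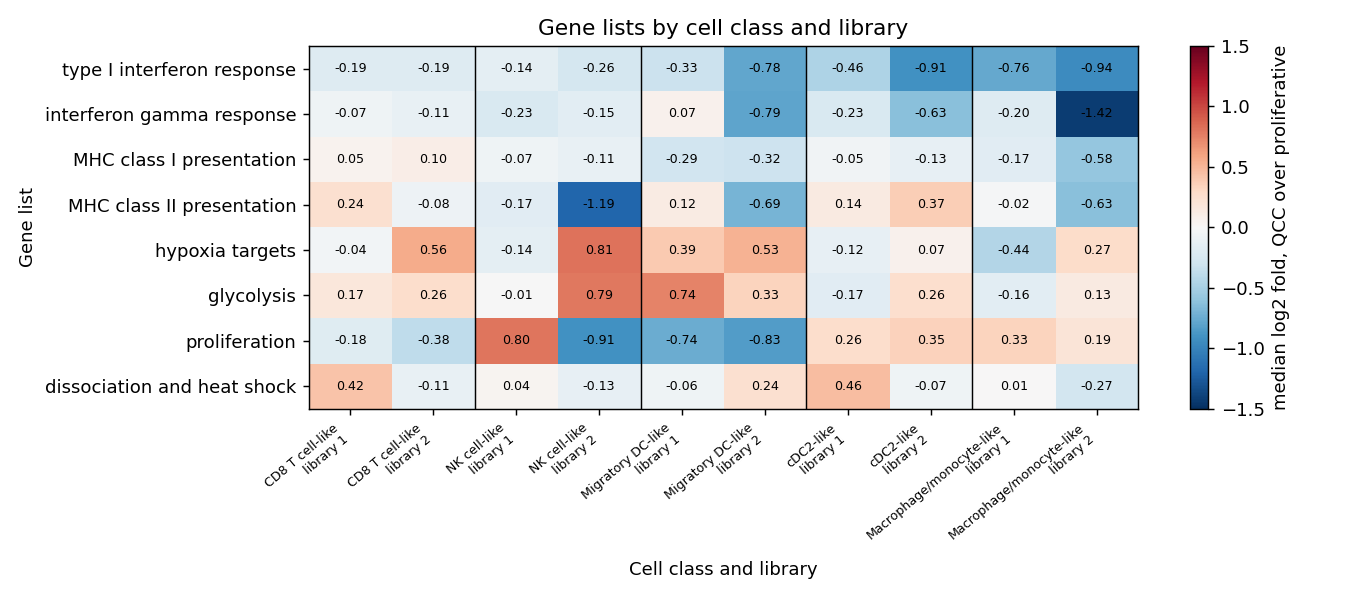
Median log2 fold of each gene list, QCC over proliferative areas, as printed in each square, for 5 cell classes with library 1 and library 2 side by side. The type I interferon list lay at -0.76 and -0.94 in macrophage/monocyte-like cells and at -0.46 and -0.91 in cDC2-like cells.

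In migratory dendritic cell (mDC)-like cells, which carry antigen to lymph nodes, glycolysis and hypoxia lists were higher and type I interferon and proliferation lists lower in QCC areas. The glycolysis list had a median of 0.57 (0.74 and 0.33; camera adjusted p = 5.94e-05), with 0 of 15 members past the threshold over all genes or over the list alone. The hypoxia list had a median of 0.48 (0.39 and 0.53; camera adjusted p = 1.67e-04), with 0 of 15 and 1 adjusted over the list alone. Type I interferon genes had a median of -0.48 (-0.33 and -0.78; camera adjusted p = 8.47e-06, 0 of 13 and 2 adjusted over the list alone). The proliferation list had a median of -0.81 (-0.74 and -0.83; camera adjusted p = 1.34e-05, 0 of 12 past either). All 4 had an adjusted p = 0.550 with an estimated correlation, and they are 4 of 12 lists that passed in camera in this class. The bound on free RNA was 45.7% of UMIs in QCC against 32.7% in proliferative areas of library 1. In library 2 it was 15.3% against 25.4%. At that bound, free RNA was over 50% of the counts of an area for 2867 of the 5412 genes tested. Values of single genes, none of which passed, included the costimulatory receptor Tnfrsf9 (1.77 ± 0.28, SE, n = 2 libraries; adjusted p = 0.35) and the chemokine Ccl8 (-3.13 ± 0.46). Over 5412 genes 0 passed in edgeR's quasi-likelihood test, with 353 at an unadjusted p under 0.05, and DESeq2 called 0. With neighbour doublets left out 47 rose and 50 fell, and without a filter on low counts 25 rose and 35 fell. Fits without 1 sum called 302, 161, 27 and 5 genes without QCC areas of library 1, of library 2, and proliferative areas of library 1 and of library 2. Without QCC areas of library 2 type I interferon (adjusted p = 0.193) and proliferation (0.0807; 0.197 with neighbour doublets left out) ended, without QCC areas of library 1 glycolysis (0.356), and without proliferative areas of library 2 hypoxia (0.106).

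In NK cell-like cells Gzmf fell by 2.90 (SE 0.34, n = 2 libraries; adjusted p = 0.00901), a value that rested on library 2 with 60 against 3258 UMIs, while library 1 held 3 against 5. The glycolysis list rose (median 0.46, -0.01 and 0.79; camera adjusted p = 1.71e-05, adjusted p = 0.580 with an estimated correlation), with 0 of 14 members past the threshold over all genes and 5 adjusted over the list alone. The hypoxia list had a median of 0.40 (-0.14 and 0.81; camera adjusted p = 0.0026, adjusted p = 0.580 with an estimated correlation), with 0 of 17 past either. Values that did not pass included Cd160, an NK receptor (-1.19 ± 0.23), Cd7 (-1.05 ± 0.20) and Capg (0.93). Sub-cluster cT0, led by Klra4 and Klra8, held 20.6% of these cells in QCC against 59.5% in proliferative areas of library 2. Over 5521 genes only Gzmf passed in edgeR's quasi-likelihood test, with 304 at an unadjusted p under 0.05, and DESeq2 called 0. On simulated counts of this class without change the test called 0.7 genes on average. The call ended with up to 20% mitochondrial UMIs (-1.75, adjusted p = 0.777) and under the hashtag ratio rule (-2.94, 0.549), and Gzmf changed sign without proliferative areas of library 2 (2.97, adjusted p = 5.32e-04). Fits without 1 sum called 8, 6, 36 and 4 genes without QCC areas of library 1, of library 2, and proliferative areas of library 1 and of library 2, and the fit without the block 0. Both lists ended without proliferative areas of library 2 (adjusted p = 0.569 and 0.424, the hypoxia list with its sign changed), and the hypoxia list also without QCC areas of library 2 (0.10) and without a filter on low counts (0.195).

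Cluster c8, led by Tslp, Wfdc2, Krt8 and Krt18, stayed unnamed. Macrophage/monocyte was the only class with enough markers detected in it (4) to give a name, at a score of -0.724. The 10 leading genes of c8 held 0 markers of that class and 2 of the epithelial/tumour class. In c8 the MHC class II list was lower (median -0.90, -1.11 and -0.68; camera adjusted p = 2.44e-11, adjusted p = 0.686 with an estimated correlation), with 0 of 10 members past the threshold over all genes and 7 adjusted over the list alone. It was 1 of 11 lists that passed in camera in c8. The bound on free RNA was 14.9% of UMIs in QCC against 30.6% in proliferative areas of library 1. In library 2 it was 14.5% against 11.1%. At that bound, free RNA was the larger part of the counts of an area for 2288 of the 10441 genes tested. Whether free RNA or doublets supplied class II transcript in c8 was not tested. The proliferation list had a median of -0.78 that differed in sign between libraries (0.41 and -1.69; camera adjusted p = 4.97e-16, adjusted p = 0.686 with an estimated correlation), with 0 of 20 and 1. Without QCC areas of library 2 neither list passed (adjusted p = 0.382 and 0.485), and without proliferative areas of library 1 the MHC class II list did not (0.163). Over 10441 genes 0 passed in edgeR's quasi-likelihood test, with 206 at an unadjusted p under 0.05, DESeq2 called 0, and the fit without proliferative areas of library 2 called 28. Sub-cluster cT3, in which T cell genes were joined by C1qa, Cd74 and Lyz2 of macrophages, also stayed unnamed. Of the called cells nearest to it, 40.8% in library 1 and 29.0% in library 2 carried both hashtags. Without neighbour doublets its QCC and proliferative sums fell from 67 and 33 to 3 and 4 cells in library 1. In library 2 they fell from 20 and 73 to 1 and 11, so cT3 may not be a class of single cells. Over its 8824 genes 0 passed, with 392 at an unadjusted p under 0.05, DESeq2 called 2, and fits without 1 sum called from 4 to 18, the most without QCC areas of library 1.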

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

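Tests of doublets in the interferon pattern, of the sub-cluster share and free RNA in the hypoxia pattern, and class I and Ptprc levels by tag or against all cells were chosen only after the result was seen.

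Differences of a list's change between classes were tested in fits that joined the 4 sums of each class compared. Only lists that had already passed in camera in opposite directions in those classes, in both libraries, were tested. The same sums served for that choice, so a pass here was likely beforehand and adds no separate evidence. Each that passed lost its call with an estimated correlation. For MHC class II presentation the median change of cDC2-like cells lay above that of macrophage/monocyte-like cells by 0.531 (camera adjusted p = 9.45e-04, adjusted p = 0.949 with an estimated correlation), of NK cell-like cells by 0.938 (7.72e-05 and 0.664) and of cluster c8 by 1.13 (3.84e-09 and 0.621). For proliferation the change of macrophage/monocyte-like cells lay above that of CD8 T cell-like cells by 0.636 (camera adjusted p = 2.41e-18, adjusted p = 0.310 with an estimated correlation), of mDC-like cells by 1.10 (2.48e-14 and 0.577) and of sub-cluster cT3 by 0.491 (9.75e-13 and 0.544). For T cell effector function the change of mDC-like cells lay above that of cDC2-like cells by 1.00 (a value of 0.9995; 0.0038 and 0.468) and that of c8 above cDC2-like cells by 1.04 (0.0421 and 0.621), while that of CD8 T cell-like cells above cDC2-like cells, by 0.476, did not pass (0.124). For monocyte recruitment chemokines cT3 lay above cDC2-like cells by 1.09 (5.4e-05 and 0.526). Most cells of cT3 were among the neighbour doublets, so its differences may not be those of single cells.

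Cells without a hashtag, which the comparison leaves out, were nearest to the fibroblast-like class in 79 of 155 called cells (51.0%, exact interval 42.8 to 59.1) in library 1 and 17 of 78 (21.8%, 13.2 to 32.6) in library 2, against 2.68% and 1.90% of all called cells. Shallow or damaged cells were argued against as the cause, since untagged fibroblast-like cells had 0.957 of the median UMIs of tagged ones in library 2 and 1.17 in library 1. Low transcript of class I MHC, which a hashtag antibody may bind, remains open. Fibroblast-like cells carried 0.738 of the class I level of cluster c8 in library 1 and 0.650 in library 2, between the bounds set for and against, and c8 was itself 16.4% untagged in library 1. As a class they lay above all cells in library 1, at 7635 against 6973 class I CPM, and below all cells in library 2, at 6629 against 7267. Their untagged cells carried less than their tagged ones, at 6711 against 8574 CPM in library 1 and 3998 against 7397 in library 2. Transcript of Ptprc (CD45), another protein that such antibodies may bind, differed more, at 2.50 against 60.9 CPM in library 1 and 3.99 against 62.9 in library 2. That explanation was not tested and stays open too; c8 carried 27.4 and 19.2 CPM of Ptprc and was 16.4% and 1.97% untagged. The antibodies' targets are not given in the sources used here. Shares of fibroblast-like cells and collagen sums rest on the tagged part of these cells.

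The type I interferon list was lower in macrophage/monocyte-like cells of QCC areas in both libraries. A different mix of clusters c0 and c21, the latter led by interferon-induced genes, was argued against as the whole cause, since outside them the list median was -0.61 in library 1 and -0.71 in library 2 (spread 0.14), against -0.69 and -0.96 over all cells of the class. These medians were taken from plain CPM plus 2 without TMM scaling, so they differ from the -0.76 and -0.94 of the report. With neighbour doublets left out the medians were -0.763 and -1.28, which cannot decide on hidden doublets. The filter dropped cells from a neighbour share of 0.267 in library 1 and 0.2 in library 2. The mean share in QCC and proliferative cells of this class was 17.2% and 17.7% in library 1 and 17.4% and 18.5% in library 2. Doublets of 2 cells of this class may thus remain. Free RNA is shared by both areas of a library and was not weighed by a separate test here. The estimated correlation ended the call of the list, and the pattern is not called biological. No biological explanation was tested.

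The hypoxia list was higher in CD8 T cell-like cells through library 2 alone, so it is not called biological. From plain CPM plus 2 without TMM scaling, as used for these tests, its median was 0.45 in library 2 and -0.07 in library 1, against 0.56 and -0.04 in the report. A larger share of the Gzmf-led sub-cluster cT6 was narrowly argued against as the cause by the measure chosen, which averages both libraries. Without cT6 the median over all 21 measured members of that mean was 0.221, against 0.25 with all cells. The spread of 0.033 was taken across list members, which are not independent. In library 2 by itself the median was 0.47 without cT6 and 0.45 with all cells, so it did not fall. Free RNA was argued against, since it could supply 9.94% of the UMIs of the median member in library 1 and 2.51% in library 2. What remains open is a difference between the areas of library 2 alone, which no further library could test.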

How the results depend on the processing

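Leaving out neighbour doublets was chosen only after the result was seen; all other alternatives were planned. Scrublet marked 0 cells, so keeping its doublets equals the reported result and gave no separate value. Where an alternative below moved a result, the cause was not tested, unless stated.

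The library block decided the counts of changed genes: without the block, 0 genes were called in all cells (73 with it), 0 in CD8 T cell-like cells (162), 1 in cDC2-like cells (77), 0 in macrophage/monocyte-like cells (7) and 0 in NK cell-like cells (1). The mDC-like, c8 and cT3 counts stayed at 0. Lists past the threshold in CD8 T cell-like cells went from 8 to 5, and the log2 share difference of mDC-like cells from -0.18 to 0.0134. Of the single genes and lists named, 50 kept their side of the threshold without the block and 108 lost their call in the same direction.

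Leaving out each of the 4 sums in turn used a fit with area only, in which a lone sum is assumed to vary like the other area. Changed genes then ranged from 0 to 0 in all cells, 0 to 48 in CD8 T cell-like, 29 to 58 in cDC2-like, 12 to 164 in macrophage/monocyte-like, 5 to 302 in mDC-like and 4 to 36 in NK cell-like cells, 0 to 28 in c8 and 4 to 18 in cT3. Lists past the threshold ranged from 4 to 9 in CD8 T cell-like cells (8 with all sums), 4 to 9 in cDC2-like (7), 7 to 11 in mDC-like (12) and 2 to 11 in NK cell-like cells (4). Log2 share differences that reversed ranged from -0.62 to 2.00 for CD4 T cell-like, -1.11 to 1.46 for endothelial cell-like, -0.30 to 0.61 for macrophage/monocyte-like, -0.48 to 2.62 for mast cell/basophil-like, -1.04 to 0.62 for mDC-like and -0.62 to 0.56 for cDC2-like cells, -2.17 to 2.15 for c20, -1.45 to 2.44 for c8 and -0.58 to 0.52 for cT3. Signed -log10 p ranged from -1.07 to 2.40 for the effector list (2.35 with all sums) and -0.192 to 11.3 for the heat shock list (3.74) in CD8 T cell-like cells, and -0.53 to 9.11 for the hypoxia list in NK cell-like cells (3.16). Log2 folds ranged in CD8 T cell-like cells from -0.92 to 3.84 for Gzmc, -0.79 to 2.21 for Gzmb, -4.12 to 13.4 for Gzma, -0.19 to 1.14 for Spp1 and -0.49 to 1.69 for Apoe. In cDC2-like cells they ranged from -2.01 to 0.11 for Cxcl9, -6.30 to 0.0667 for Cxcl10 and -9.35 to 6.93 for Ccl24, in macrophage/monocyte-like cells from -0.18 to 1.80 for Cdh1 and -12.6 to 1.29 for Cxcl13, and in NK cell-like cells from -6.25 to 2.97 for Gzmf.

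An estimated correlation left 0 lists past the threshold in each of the 8 sets of sums, against 11 in all cells, 8 in CD8 T cell-like, 7 in cDC2-like, 10 in macrophage/monocyte-like, 12 in mDC-like and 4 in NK cell-like cells, 11 in c8 and 13 in cT3. DESeq2 size factors kept all 25 list results named. DESeq2's own test called 248 genes in all cells, 8 in CD8 T cell-like, 3 in cDC2-like, 86 in macrophage/monocyte-like and 0 in NK cell-like cells and 2 in cT3. Without a filter on low counts, more genes entered and 421 were called in all cells, 707 in macrophage/monocyte-like, 60 in mDC-like and 28 in NK cell-like cells, 38 in c8 and 72 in cT3.

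A floor of 500 UMIs gave 4 changed genes in macrophage/monocyte-like cells and 2 in cT3, and 154 of the single genes and lists named kept their side of the threshold against 4 that lost their call. A floor of 2000 UMIs gave 2 in macrophage/monocyte-like, 4 in mDC-like and 0 in NK cell-like cells, 7 lists in NK cell-like cells, and reversed the log2 share differences of c20 (-0.14, from 0.09) and cT3 (-0.0263, from 0.03). Up to 20% mitochondrial UMIs gave 35 changed genes in all cells, 4 in macrophage/monocyte-like, 3 in mDC-like and 0 in NK cell-like cells. The hashtag ratio rule gave 46 in all cells, 1 in macrophage/monocyte-like and 0 in NK cell-like cells and 10 in cT3, and a log2 share difference of -0.0203 for cT3. With neighbour doublets left out there were 0 in macrophage/monocyte-like and 97 in mDC-like cells and 2 in cT3. There 2 lists passed against 13, from sums of only 1 to 11 cells. With genes that free RNA can supply left out, which removed most tested genes of those classes, 45 were called in cDC2-like cells. Of these, 33 were also called in the main fit. In macrophage/monocyte-like cells 0 were called. With immune classes as the denominator the log2 share differences of B cell-like (-2.95, from -3.00) and pDC-like cells (-1.98, from -2.05) passed the threshold. At Leiden resolution 0.6 all 14 shares that could be matched kept their direction and their side of the threshold.

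The type I interferon list in all cells, cDC2-like and macrophage/monocyte-like cells, the interferon gamma list in cDC2-like and macrophage/monocyte-like cells, and both fibroblast lists in all cells passed under each alternative run for lists except the estimated correlation. Leaving out genes that free RNA can supply was not run for lists. At this depth simulated 2-fold changes were recovered at between 8.36% in c8 and 66.5% in CD8 T cell-like cells, and sums of cDC2-like cells held as few as 29 cells and those of cT3 as few as 20. Whether depth, cell number or spread set the recovery was not tested.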

Other observations

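The tests of small classes (at least 8 cells per sum) were all chosen only after the result was seen, as were the genes named here.

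Tagged fibroblast-like cells of QCC areas carried less of the inflammatory fibroblast list. Of the called cells nearest to this class, 51.0% in library 1 and 21.8% in library 2 had no hashtag and were left out. Over 6776 genes, 20 rose and 41 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with DESeq2 calling 14 higher and 22 lower, 32 of them shared. The chemokine Cxcl12 fell by 3.24 (SE 0.40, n = 2 libraries; -2.57 and -4.13), and the alarmin Il33 (-2.20), the collagen Col4a1 (-2.30) and the metalloprotease inhibitor Timp1 (-1.96 ± 0.25) fell with it. The stromelysin Mmp10 rose by 4.20 ± 0.41 (4.10 and 2.67) and the retinoic acid binding protein Crabp1 by 2.51 ± 0.30. The inflammatory fibroblast list had a median of -0.93, with all 19 measured members below 0 (camera adjusted p = 4.34e-14, adjusted p = 0.852 with an estimated correlation). The macrophage genes C1qa (1.80) and Arg1 (2.55) rose in the same cells, and the sums held as few as 10 cells. The bound on free RNA was 39.9% of UMIs in QCC against 25.2% in proliferative areas of library 1 and 42.9% against 24.5% in library 2, and at that bound it was over 50% of the counts of an area for 26 of the 61 genes called. With neighbour doublets left out, or with up to 20% mitochondrial UMIs, 0 genes passed in edgeR (448 and 653 at an unadjusted p under 0.05), as in the fit without the library block. Fits without 1 sum called 70 higher and 167 lower without QCC areas of library 1, 89 and 100 without those of library 2, 20 and 23 without proliferative areas of library 1 and 22 and 76 without those of library 2.

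In neutrophil-like cells of QCC areas the MHC class II list was higher and the inflammatory myeloid list lower. Cd74, the class II invariant chain, rose by 2.09 and H2-Aa by 2.44, while the neutrophil chemokine Cxcl3 fell by 2.94 (SE 0.40) and Tnf fell by 2.82. In all, 17 genes were higher and 20 lower of 2055 in edgeR, and 5 and 7 in DESeq2. Each fit without 1 sum called fewer in both directions, and the full fit without the library block called 0 and 0. The MHC class II list had a median of 2.03 (camera adjusted p = 1.51e-09, adjusted p = 0.668 with an estimated correlation), the inflammatory myeloid list one of -1.20 (9.64e-10 and 0.644) and the type I interferon list one of -0.76 (-0.71 and -0.86; 1.26e-06 and 0.644). The bound on free RNA in this class was 16.4% of UMIs in QCC against 7.55% in proliferative areas of library 1 and 30.5% against 17.6% in library 2. At that bound, free RNA was over 50% of the counts of an area for 23 of the 37 genes called. In cDC1-like cells the glycolysis list had a median of 0.46 (0.59 and 0.32; 2.96e-11 and 0.641) and the hypoxia list one of 0.55 (0.56 and 0.35; camera adjusted p = 5.36e-07, adjusted p = 0.641 with an estimated correlation), with 20 genes higher and 6 lower of 8060 in edgeR and 0 in DESeq2. Without QCC areas of library 1 or of library 2 edgeR called 0, without proliferative areas of library 1 it called 13 higher and 17 lower, without those of library 2 and without the library block 1 each, and with neighbour doublets left out 5 higher and 2 lower. Free RNA at its bound was over 50% of the counts of an area for 14 of the 26 genes called.

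Within the macrophage/monocyte-like class the type I interferon list was lower in QCC areas in each of the 5 clusters with at least 25 cells per sum. Its within-library medians were -0.54 and -0.59 in c0, -0.16 and -0.60 in c1, -0.54 and -0.43 in c2, -2.08 and -0.62 in c5 and -0.27 and -0.87 in c6. In pDC-like cells 0 of 4810 genes passed in edgeR, with 35 at an unadjusted p under 0.05, and DESeq2 called 1. With neighbour doublets left out 7 were higher and 26 lower, and without QCC areas of library 2 34 were higher and 3 lower.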
